A study of Mus musculus with 10 samples.

How the data were processed

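Gene expression was measured on 10 Affymetrix arrays of total RNA from mouse secondary inducible embryonic fibroblasts of a hybrid mouse strain, 2 arrays for each of 5 groups. The groups were an uninduced control in 0.5% serum and 4 cohorts induced with doxycycline in 15% serum, labelled as 2 ug/ul, with 0, 1, 2, or 3 or more average divisions in 96 h. The labels call the numbered samples biological replicates in the control and in the cohort of 3 or more divisions and only replicates in the other cohorts. Nothing in them states separate cultures or animals, so the spread between the 2 samples per group may be technical in part. The p-values of the main fit rest on that spread, which holds a difference between the replicate numbers that recurs across the groups. The control and the cohort of 3 or more divisions form an earlier registered set of 4 arrays, and the other cohorts a later set of 6. No group spans both sets.

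The authors deposited a single table of linear intensity for 45101 probe sets, with values from 5.7 to 26572. Per the submitters' processing notes, RMA was named for the 4 arrays of the earlier set. No tool is named for the other 6 in the sources used here, nor is the version of RMA or whether all arrays were normalized together. From the values, the deposited intensities had array medians of 31.4 to 33.95 and near-equal distributions in both sets. The planned tests assumed log2 values. As the values proved linear, the alternative written for that case became the main setting, a floor of 1, which moved 0 values, log2, and quantile normalization of the 10 arrays. No detection calls were given, so which genes lay above background is not known, and differences of dim genes are compressed on this scale.

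Probe sets were named through the platform's gene table. Of the probe sets, 34945 had 1 gene, 932 had several genes and 9211 were not listed there, 9160 of which were not control probe sets, and only those with 1 gene were named. By gene ID 34741 of the 34945 were found in the RefSeq gene table, which changed 0 symbols. The probe set with the highest mean over the 10 arrays stood for its gene, which left 18193 genes, 9010 of them with more than 1 probe set. No genome build is given for the table, so no coordinates are printed. The reprogramming factors show how probe sets of a gene can differ, with 2 probe sets of Klf4 at 8.65 and 8.99 on replicate 1 of the cohort of 3 or more divisions, against 10.35 and 9.31 on replicate 1 of the control.

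Tests were run with limma 3.58.1 in R 4.3.3. A linear model with the 5 groups was fitted to all 10 arrays with lmFit and eBayes, which shares the spread over groups with 5 residual degrees of freedom, and the slope over 0, 1 and 2 divisions was fitted to 6 arrays with 4. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 18193 genes were called, two-sided, and calls of at least 2-fold were counted beside them. The comparisons were each cohort with the control, 2 and 3 or more divisions with 0, the slope, and the overlap of the calls after 0 and after 3 or more divisions. For 24 gene lists with 505 of 533 genes measured, limma's camera test with a preset correlation of 0.01 was adjusted over the lists of a comparison. Camera with an estimated correlation passed 0 lists in each of the comparisons. This loss does not come from gene correlation alone. For 2 divisions against 0 the immediate early list had an estimated correlation of -0.006, below the preset one. Its camera adjusted p still went from 0.000184 to 0.126. Listed genes outside the table were not analysed here. Groups, tests, gene lists, named-gene rule and the other settings, apart from 3 added ones, were fixed before the data were examined.

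The named genes were the reprogramming factors, Nanog, Cdh1, Epcam, Fut4 and Thy1, the 6 largest rises and 6 largest falls per comparison among called genes with arrays of the groups apart, and up to 3 called members of each list, or the largest member where none was called.

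The replicate numbers were checked as a pairing from the data, since the labels state no shared culture. This used genes with a mean above the median of all genes. Deviations of same-numbered arrays from their group means correlated with r of 0.477 to 0.872 in all 10 pairs of groups. The principal component that held 21.1% of the variance parted the numbers in each of the 5 groups. All pairs deviated together, so the numbers were taken to pair the samples. The spread of the fit without the block therefore holds a difference that recurs in the groups. Its 5 residual degrees of freedom do not come from independent pairs. The fit without the block stayed the main design as planned, and the blocked value is given where it changes the call of a list or moves a count given for a comparison or for a list described there by over 1.5 times. All calls of the unblocked fit, in each comparison, were also made with the block, with 0 opposite signs.

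The method was tested on simulated data with the spread of the 18193 genes and 200 changed genes. The simulated noise was drawn independently per gene and array, without the component shared by arrays of the same replicate number. The rates given here may therefore not hold for the real arrays. In the simulation of 3 or more divisions against the control 64% of genes changed by 1 on the log2 scale and 86% of those changed by 2 were recovered, with 11 false calls. For 0 divisions against the control these were 56% and 92%, with 11 false calls, and for the slope 47% and 85%, with 10. Other settings tried were the replicate block, fits to the compared groups only, both together, 8 arrays in the slope, no quantile normalization, median centring, a floor of 16, other rules for probe sets, a filter on dim genes, eBayes with trend and robust, thresholds of 0.01 or 2-fold, estimated camera correlation, fry, and leaving out each array. The fits without 1 array had no block and left the replicate numbers unbalanced between the groups. Calls lost or gained in them may therefore come from the replicate number as well as from the cohort. Control probe sets of Actb and Gapdh were read for RNA quality and stayed out of the tests. The Gapdh 3-prime minus 5-prime difference ran from 0.03 to 0.27 and that of Actb from 0.27 to 0.49.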

Results

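Messenger RNA was measured on 10 Affymetrix mouse arrays in secondary inducible embryonic fibroblasts, which carry doxycycline-inducible transgenes for the reprogramming factors Pou5f1, Sox2, Klf4 and Myc. The 5 groups held 2 arrays each. The control cells were uninduced and kept in 0.5% serum for 96 h. The induced cells received doxycycline in 15% serum for 96 h and were labelled as cohorts with an average of 0, 1, 2, or 3 or more divisions. How the cohorts were parted is not given in the sources used here. The titles of the arrays of 3 or more divisions name only the induction, so whether these cells were parted at all is not known. The question posed by this design was which genes had moved in the initial phase of reprogramming. It also asked whether induced cells labelled with an average of 0 divisions already differed from the starved cells. The deposited intensities had near-equal distributions, with array medians of 31.4 to 33.95, and the number of arrays limited the precision. Components were taken over genes with a mean above the median of all genes. Across the arrays, the main principal component held 62.2% of the variance and ran from the control to the cohort of 3 or more divisions. The next component held 21.1% and parted replicate 1 from replicate 2 in each of the 5 groups. The 3-prime minus 5-prime difference of the Actb control probe sets, a sign of RNA quality, was 0.28 and 0.30 on the log2 scale in the control and 0.45 on both arrays of the cohort of 3 or more divisions. A control probe set for the 18S ribosomal RNA, looked at after its values were seen, read 8648 and 5311 in the control against 1747 and 1553 in that cohort.

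Induced cells labelled with an average of 3 or more divisions differed from the starved control in epithelial, keratin, growth and matrix genes. Cdh1, the adhesion molecule E-cadherin of epithelial cells, rose from 3.37 ± 0.21 to 9.31 ± 0.16 (log2 intensity, SD, n = 2 per group), a log2 change of 5.93 ± 0.40 (SE) or 61.0-fold. Among called genes whose arrays did not overlap between the groups, the largest rises were those of Aldh3a1, an aldehyde dehydrogenase (154-fold), Mal, a proteolipid of apical transport (134-fold), the keratin gene Krt16 (102-fold), Fetub (95.8-fold), Ces1f (76.8-fold) and Slurp1, a secreted protein of keratinocytes (70.4-fold). Mal, Krt16 and Cdh1 read 3.23 to 3.76 on the control arrays, where Nanog read 3.28 and 3.51. No detection calls were given, so folds against such dim readings, here and in the other comparisons, are not exact and their order is not fixed. The largest falls were those of C1qtnf3 (a log2 change of -5.52), the tendon gene Tnmd (-5.31), the angiotensin receptor gene Agtr2 (-5.02), the kinase gene Nrk (31.95-fold lower), the collagen gene Col8a2 (-4.99) and Dner (-4.96). In all, 5020 of 18193 genes passed limma's test at an adjusted p under 0.05, 2895 higher and 2125 lower, and 2339 of them had moved at least 2-fold.

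Genes of cell growth and division rose together. All 25 measured ribosome biogenesis genes rose, with a median log2 change of 1.70, led by Dkc1 of the small nucleolar particles (2.83 ± 0.13, SE) and the RNA polymerase I subunit gene Polr1b (2.58 ± 0.21). Limma's camera test gave this list an adjusted p of 2.29e-17, and an adjusted p of 0.177 with an estimated correlation. Of 29 mitosis genes 28 rose (29 adjusted over the list alone), with a median of 1.85, among them Anln (2.34), Aurka (2.26) and Bub1b (2.20), and the list passed (adjusted p = 6.03e-16, and adjusted p = 0.216 with an estimated correlation). DNA replication genes rose in 22 of 29 cases (24 adjusted over the list alone), led by Uhrf1 (2.73), Cdt1 (2.55) and Mcm5 (2.32), and that list passed as well (adjusted p = 1.22e-11, and adjusted p = 0.216 with an estimated correlation). Of 15 glycolysis genes 12 rose (13 adjusted over the list alone), including the lactate transporter gene Slc16a1 (2.77) and the hexokinase gene Hk2 (2.45), with adjusted p = 1.76e-05, and adjusted p = 0.177 with an estimated correlation. Oxidative phosphorylation genes rose in 14 of 22 cases (15 adjusted over the list alone) by smaller amounts, a median of 0.48, with Uqcrc1 at 1.29 (adjusted p = 4.91e-06, and adjusted p = 0.216 with an estimated correlation). Chromatin regulators rose in 17 of 31 cases and fell in 2 (18 and 3 adjusted over the list alone), led by the helicase gene Hells (2.34) and the histone methyltransferase gene Ezh2 (1.81), with adjusted p = 0.00017, and adjusted p = 0.287 with an estimated correlation.

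Epithelial genes moved in part. Of 30 measured members 7 rose and 0 fell, by all genes and adjusted over the list alone, with the desmosome gene Dsp at 5.66 ± 0.59 (SE) and Krt19 at 5.35 ± 0.30 beside Cdh1, while the list's median was 0.16 (adjusted p = 0.0165, and adjusted p = 0.177 with an estimated correlation). The call of this list was lost with a floor of 16 (adjusted p = 0.0584) and without replicate 1 of the cohort (adjusted p = 0.0549). Epcam, read by a probe set that can match several transcripts, stood at 6.36 ± 0.28 against 6.25 ± 0.20 (SD, n = 2) and did not pass (adjusted p = 0.758). Its other probe set read 3.70 and 4.40 in the cohort and 3.36 and 3.55 in the control, and was not the one tested. Keratinocyte markers rose in 9 of 14 cases, also adjusted over the list alone, with Krt16 at 6.67, Krt14 at 6.04 and Krt6a at 3.95 (adjusted p = 0.000172, and adjusted p = 0.177 with an estimated correlation).

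Fibroblast genes fell. Of 29 fibroblast matrix genes 21 fell and 0 rose, also adjusted over the list alone, with a median of -1.20, including Dpt (-4.51 ± 0.39, SE), Mfap5 (-3.35) and the PDGF receptor gene Pdgfra (-2.95), and camera gave adjusted p = 1.38e-10, and adjusted p = 0.177 with an estimated correlation. Contractile and TGF-beta response genes fell in 9 of 19 cases (10 adjusted over the list alone), led by the myosin kinase gene Mylk (-2.86), with adjusted p = 1.26e-06, and adjusted p = 0.369 with an estimated correlation. Mesenchymal regulators fell in 10 of 22 cases (12 adjusted over the list alone), with Osr1 at -2.09 and the cadherin gene Cdh11 at -1.97 (adjusted p = 3.79e-05, and adjusted p = 0.216 with an estimated correlation). Thy1, a surface marker of fibroblasts, fell by 0.85 ± 0.25 (adjusted p = 0.0398). Interferon response genes fell in 11 of 21 cases and rose in 1 (13 and 1 adjusted over the list alone), with Ifit3 at -3.16 and Gbp2 at -2.09 (adjusted p = 3.88e-05, and adjusted p = 0.26 with an estimated correlation).

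Of the reprogramming factors, Pou5f1 rose by 4.17 ± 0.35 (SE, 18.0-fold) and Myc by 3.06 ± 0.47, while Klf4 fell by 1.93 ± 0.19 and Sox2 read 3.93 ± 0.12 against 3.83 ± 0.39 (SD, n = 2). The other Klf4 probe set, not the one tested, read 8.99 and 9.01 against 9.31 and 9.47 in the control. Where these probe sets lie relative to the transgenes is not given in the sources used here, so they do not test the induction. Of the 4 factors 2 rose and 1 fell, also adjusted over the list alone, and they did not pass as a list (adjusted p = 0.544). Of 35 pluripotency network genes 3 rose and 4 fell (3 and 3 adjusted over the list alone), with a median of 0.02 (adjusted p = 0.953). Mybl2 (2.08) and Alpl (1.56) were higher and Klf2 lower (-3.22). Nanog, a core factor of pluripotent cells, had a log2 change of -0.05 ± 0.16 (SE) and did not pass. Fut4 read 3.75 ± 0.17 against 3.82 ± 0.17 (SD) and did not pass.

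The other lists did not pass camera in this comparison. Adjusted over the list alone, 7 neural genes rose and 1 fell, 5 immediate early genes rose and 7 fell, 0 lineage regulators rose and 1 fell, and the counts of the remaining 7 lists were those over all genes given here. Markers of other cell types moved in both directions. Of 14 neural and glial genes 6 rose and 1 fell, with Stmn2 at 5.82 ± 1.08 (SE), Tubb3 at 3.33 and Map2 at -2.02 (list adjusted p = 0.445). Among 18 macrophage markers Cd68 rose (3.54) and Lyz2 fell (-1.39), with a list adjusted p of 0.861. Endothelial markers rose in 1 of 15 cases, Tek (2.44), and fell in 3, including Flt1 (-2.03, list adjusted p = 0.953). Adipocyte markers held 1 rise, Pparg (2.00), and 1 fall, the lipoprotein lipase gene Lpl (-4.77, list adjusted p = 0.769), and skeletal muscle markers 2 rises and 2 falls, the largest in size Tnnc1 (-0.82, list adjusted p = 0.867). Of 20 immediate early genes 5 rose and 3 fell, with Fosl1 at 2.62 and Fos at -2.06 (list adjusted p = 0.964). Among 18 CDK inhibitors and p53 targets the apoptosis genes Perp (2.77) and Bbc3 (1.52) rose and 2 fell, including the inhibitor gene Cdkn1c (-4.70, list adjusted p = 0.953). Of 17 cholesterol synthesis genes only Dhcr7 passed (1.28, list adjusted p = 0.544), and among 28 lineage regulators 1 rose and 2 fell, Msx1 by the most (-1.59, list adjusted p = 0.317). Hox genes fell in 3 of 23 cases and rose in 1, with Hoxa10 at -1.52. That list did not pass (adjusted p = 0.0709), and it passed with the replicate number as a block (adjusted p = 0.00145, and adjusted p = 0.344 with an estimated correlation). It also passed in 5 other settings that kept both arrays of each compared group. Its median went from -0.56 to -0.98 without control replicate 1 and to -0.83 without replicate 2 of the cohort. These 2 fits had no block and left the replicate numbers unbalanced between the groups. Hox genes differed between the replicate numbers, so these 2 shifts are no support for a cohort effect.

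With the replicate block the counts of falls were 17 for contractile, 12 for Hox, 8 for immediate early, 6 for lineage, 6 for CDK inhibitor and p53, 4 for chromatin, 2 for adipocyte and 1 for epithelial genes. Those of rises were 4 for CDK inhibitor and p53, 3 for cholesterol synthesis, 2 for endothelial and 1 for matrix genes. Doxycycline, serum and division all differed between these 2 groups, so the comparison does not part them. Leaving out 1 array gave from 4025 calls down to 2701, the last without replicate 2 of the cohort, and 23 of the 80 named genes past the threshold lost their call in at least 1 of these fits, among them C1qtnf3, Agtr2, Klf2, Pdgfra, Hk2 and Thy1.

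**Figure D1:**
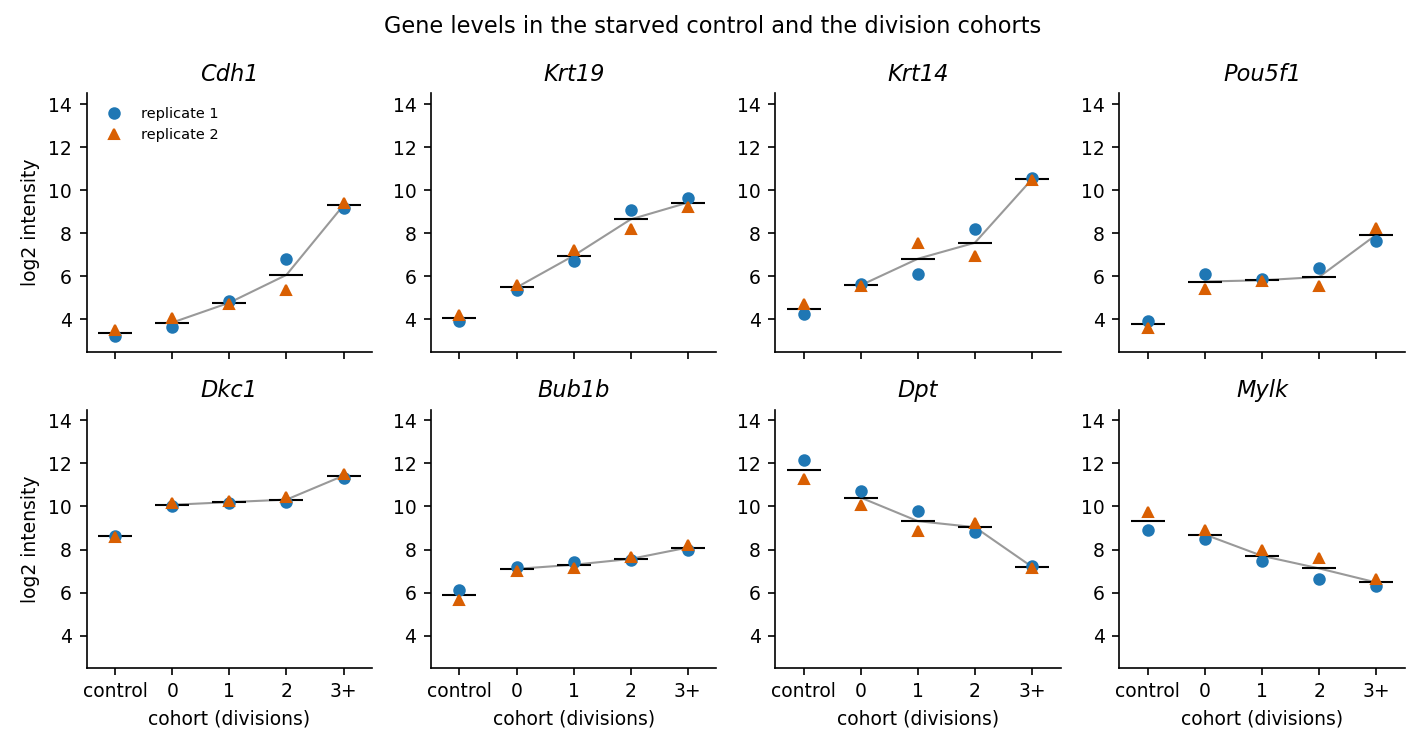
Normalised log2 intensity of 8 genes in the starved control and the induced cohorts of 0, 1, 2 and 3 or more divisions. Circles and triangles are replicates 1 and 2, the dash is their mean, and the line joins the means of the induced cohorts, with Cdh1 between 9.19 and 9.42 in the cohort of 3 or more divisions and between 3.23 and 3.52 in the control.

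In induced cells labelled with 0 divisions, lists of growth genes shifted up against the starved control, and the epithelial list did not pass the same test. Whether these lists differed from each other was not tested. Herc1, a large ubiquitin ligase gene, rose from 6.94 ± 0.01 to 10.50 ± 0.15 (SD, n = 2), a log2 change of 3.56 ± 0.12 (SE) or 11.8-fold. Rises were ranked among called genes whose arrays did not overlap between the groups. The other large rises were those of Mfsd6 (4.59-fold), Gch1 (4.58-fold), the noncoding RNA gene Snhg4 (3.87-fold), Tspan13 (3.84-fold) and Cdca7l (3.75-fold). Falls were ranked in the same way. Crispld2 (-2.28), the matrix gene Smoc2 (-1.91), Dock10 (-1.68), C1qtnf2 (-1.68), Lgr5, a receptor of Wnt signalling (-1.60), and Adcy7 (-1.50) fell by the most. In total 54 of 18193 genes passed, 40 higher and 14 lower (16 and 9 with each array centred on its median), and 41 of them had moved at least 2-fold. The 3-prime minus 5-prime difference was 0.33 and 0.27 for Actb against 0.28 and 0.30 in the control, and 0.11 and 0.10 for Gapdh against 0.05 and 0.03 in the control.

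Mitosis genes shifted up as a list, with a median of 1.11 and 29 of 29 changes above 0, although 0 of them passed singly over all genes, 22 with the replicate block and 28 adjusted over the list alone (camera adjusted p = 2.44e-29, and adjusted p = 0.247 with an estimated correlation). Birc5, the largest, read 8.51 ± 0.11 against 7.22 ± 0.41 (SD). At an unadjusted p under 0.05 limma counted 2136 genes in this comparison. Ribosome biogenesis genes shifted by a median of 0.80, with 4 of 25 past the test, among them Dkc1 (1.47), Wdr12 (1.28) and Fbl (1.19), 18 with the block and 23 adjusted over the list alone (adjusted p = 6.64e-27, and adjusted p = 0.247 with an estimated correlation). For DNA replication the median was 0.68, Mcm7 alone passed of 29 genes (0.98), 13 passed with the block and 22 adjusted over the list alone (adjusted p = 8.59e-18, and adjusted p = 0.247 with an estimated correlation). Glycolysis genes (median 0.37, adjusted p = 4.45e-05) and oxidative phosphorylation genes (median 0.22, adjusted p = 4.04e-06) shifted up with 0 genes past the test and 5 and 1 adjusted over the list alone, both with an adjusted p of 0.247 with an estimated correlation. Chromatin regulators shifted by a median of 0.13 with 0 genes past the test and 3 adjusted over the list alone (adjusted p = 0.019, and adjusted p = 0.652 with an estimated correlation).

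Interferon response genes shifted down by a median of -0.44 (adjusted p = 1.95e-07, and adjusted p = 0.247 with an estimated correlation) and fibroblast matrix genes by -0.31 (adjusted p = 8.45e-06, and adjusted p = 0.247 with an estimated correlation). All 17 cholesterol synthesis genes lay below the control, with a median of -0.49 and Fdft1 at 9.40 ± 0.05 against 10.19 ± 0.43 (SD; list adjusted p = 6.3e-05, and adjusted p = 0.637 with an estimated correlation). Contractile genes (median -0.34, adjusted p = 0.0163, and adjusted p = 0.771 with an estimated correlation) and mesenchymal regulators (median -0.26, adjusted p = 0.0195, and adjusted p = 0.637 with an estimated correlation) shifted down too. In these 5 lists 0 genes passed singly, over all genes and adjusted over the list alone. Limma's fry, which tests the list alone, did not pass them either. Its adjusted p ran from 0.0896 for interferon genes to 0.699 for contractile genes. The epithelial list did not pass (median 0.03, adjusted p = 0.736), with 0 genes adjusted over the list alone, and Cdh1 read 3.85 ± 0.30 against 3.37 ± 0.21. Other members stood higher without passing, Krt19 at 5.48 ± 0.16 against 4.08 ± 0.20 (adjusted p = 0.114, and 0.0457 with the replicate block) and Dsp at 7.24 ± 0.80 against 6.08 ± 0.74 (adjusted p = 0.52). Krt16 read 6.54 ± 0.18 against 3.68 ± 0.12 (adjusted p = 0.0558). Pou5f1 read 5.76 ± 0.52 against 3.76 ± 0.22 (adjusted p = 0.0678), and both passed with the replicate block (adjusted p = 0.0171 and 0.0167).

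With the replicate number as a block 591 genes passed, 429 higher and 162 lower, and so did the Hox list (adjusted p = 0.0154, and adjusted p = 0.6 with an estimated correlation). The block also called 2 glycolysis genes and 1 each of the oxidative phosphorylation, chromatin and epithelial lists as higher, and 1 each of the matrix and interferon lists as lower. In the 4 compared arrays alone 0 genes passed. Without control replicate 1 or 2 the count was 32 or 7, and without cohort replicate 1 or 2 it was 6 or 4. Of 16 named genes 13 lost their call when some array was left out, while Herc1, Snhg4 and Cdca7l passed without any 1 array but not in the 4 compared arrays alone. Chromatin regulators lost the call without control replicate 2 (median 0.05) and cohort replicate 1 (0.06), and contractile genes did without the same 2 arrays (-0.15 and -0.02). Mesenchymal regulators lost it without control replicate 1 (-0.06) and cohort replicate 2 (-0.12), and cholesterol synthesis without control replicate 2 (-0.32). Hox genes gained it without control replicate 1 (-0.66) and cohort replicate 2 (-0.59), against a median of -0.23 with all arrays. These fits had no block and left the replicate numbers unbalanced between the groups, so such losses and gains may come from the replicate number. Among the brighter genes chromatin regulators (camera adjusted p = 0.0568) and mesenchymal regulators (0.0747) lost the call. This cohort was registered apart from the control, so batch, serum and doxycycline cannot be told apart from the group.

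After 1 division, induced cells stood above the starved control in growth genes and in single keratin genes. Aldh3a1 rose 27.4-fold, Ces1f 16.4-fold, Krt16 14.0-fold, Slurp1 13.8-fold, Herc1 9.70-fold and Pcolce2 9.64-fold. Krt19 rose from 4.08 ± 0.20 to 6.96 ± 0.35 (SD, n = 2) and was the only epithelial gene of 30 past the test. Dner (22.6-fold lower), Lpl (a log2 change of -3.64), Kcne4 (-3.15), Mfap4 (-2.72), Crispld2 (-2.49) and Dpt (-2.39) fell by the most. Only called genes whose arrays did not overlap between the groups were ranked. Limma called 226 genes, 171 higher and 55 lower, and 150 of them had moved at least 2-fold. The 3-prime minus 5-prime differences were 0.42 and 0.31 for Actb and 0.22 and 0.18 for Gapdh, against 0.28 and 0.30 and against 0.05 and 0.03 in the control, and 18S read 4188 and 2549 against 8648 and 5311.

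Of 29 mitosis genes 10 rose (26 adjusted over the list alone), including Anln (1.58), Bub1b (1.40) and Kif2c (1.36), with a list adjusted p of 4.33e-25, and adjusted p = 0.344 with an estimated correlation. Ribosome biogenesis genes rose in 7 of 25 cases (22 adjusted over the list alone), with Dkc1 at 1.60 (adjusted p = 4.86e-21, and adjusted p = 0.344 with an estimated correlation), and DNA replication genes in 3 of 29 (14 adjusted over the list alone), with Mcm7 at 1.08 (adjusted p = 1.34e-12, and adjusted p = 0.344 with an estimated correlation). The glycolysis list (median 0.37, 3 genes higher adjusted over the list alone, adjusted p = 0.000149, and adjusted p = 0.344 with an estimated correlation) and the oxidative phosphorylation list (median 0.16, 0 genes adjusted over the list alone, adjusted p = 0.0153, and adjusted p = 0.559 with an estimated correlation) shifted up. The matrix list shifted down by -0.38 with Dpt past the test, also adjusted over the list alone (adjusted p = 8.17e-05, and adjusted p = 0.344 with an estimated correlation), as did the interferon list by -0.38 with 4 genes lower adjusted over the list alone (adjusted p = 1.78e-05, and adjusted p = 0.344 with an estimated correlation) and the contractile list by -0.44 (adjusted p = 0.00737, and adjusted p = 0.658 with an estimated correlation). Over all genes 0 members of the glycolysis, oxidative phosphorylation, interferon and contractile lists passed, and 0 of the contractile list did adjusted over the list alone. Pou5f1 rose by 2.05 ± 0.35 (SE, adjusted p = 0.0437). Fosl1 (2.06), Phlda1 (1.59) and Dusp6 (1.36) of the immediate early genes and the endothelial receptor gene Tek (1.66) rose, while Cdh1 read 4.78 ± 0.09 against 3.37 ± 0.21 (SD, adjusted p = 0.153).

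With the replicate block 1277 genes passed, 813 higher and 464 lower, and the Hox list passed as well (adjusted p = 0.00243, and adjusted p = 0.467 with an estimated correlation). The count was 0 in the 4 compared arrays alone, 4 without replicate 2 of the cohort, 29 without its replicate 1, 26 without control replicate 2 and 77 without control replicate 1. Herc1 was the only named gene of 28 that passed without any 1 array, and it did not pass in the 4 compared arrays alone. The block called 24 mitosis, 21 ribosome biogenesis, 13 DNA replication, 3 glycolysis, 2 epithelial and 6 immediate early genes as higher. It called 3 interferon, 1 contractile and 5 matrix genes as lower, and 1 matrix gene as higher. The cohort of 1 division was registered apart from the control, so batch, serum, doxycycline and division cannot be told apart in this comparison.

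After 2 divisions Cdh1 and Krt14 were also past the test against the control. This cohort too was registered apart from the control, so batch, serum, doxycycline and division cannot be told apart. Cdh1 rose by 2.69 ± 0.40 (SE, 6.47-fold), Krt19 23.8-fold, Dsp 13.1-fold and Krt14 8.48-fold, and the largest rises were those of Aldh3a1 (97.8-fold), Ces1f (54.8-fold), Mal (45.8-fold), Stmn2, a tubulin-binding protein of neurons (33.8-fold), and Slurp1 (31.3-fold). Dner (-4.78), Tnmd (-4.40), Lpl (-4.07), Mfap4 (-3.46), Smoc2 (-3.08) and the natriuretic peptide receptor gene Npr3 (-3.07) fell by the most. Both ranks cover only called genes whose arrays did not overlap between the groups. The test called 1114 genes, 740 higher and 374 lower, and 543 of them had moved at least 2-fold. Signs of RNA quality differed from the control too, with Actb at 0.42 and 0.49 against 0.28 and 0.30, Gapdh at 0.13 and 0.25 against 0.05 and 0.03, and 18S at 4218 and 2399 against 8648 and 5311.

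Ribosome biogenesis genes rose in 17 of 25 cases (24 adjusted over the list alone), with Dkc1 at 1.71 (adjusted p = 1.21e-18, and adjusted p = 0.27 with an estimated correlation). Mitosis genes rose in 21 of 29 cases (27 adjusted over the list alone), with Anln at 1.86 and Mki67, a marker of cycling cells, at 1.65 (adjusted p = 5.26e-21, and adjusted p = 0.27 with an estimated correlation), and DNA replication genes in 14 of 29 (20 adjusted over the list alone), with Tk1 at 1.79 (adjusted p = 3.44e-13, and adjusted p = 0.27 with an estimated correlation). The contractile list shifted by a median of -1.02, with Mylk past the test (-2.21) and 4 genes lower adjusted over the list alone (adjusted p = 1.66e-06, and adjusted p = 0.493 with an estimated correlation), and the matrix list by -0.50, with 5 of 29 lower, among them Dpt (-2.67) and Mfap5 (-1.95), and 11 lower and 1 higher adjusted over the list alone (adjusted p = 2.66e-05, and adjusted p = 0.279 with an estimated correlation). Keratinocyte markers rose in 3 of 14 cases, Krt16 (4.11), Krt14 (3.08) and Lgals7 (2.07), and in 4 adjusted over the list alone (adjusted p = 0.00979, and adjusted p = 0.27 with an estimated correlation). Immediate early genes rose in 5 of 20 cases, also adjusted over the list alone, led by Fosl1 (2.22; adjusted p = 0.036, and adjusted p = 0.27 with an estimated correlation). The glycolysis list (0.41, adjusted p = 0.00037, and adjusted p = 0.27 with an estimated correlation), the oxidative phosphorylation list (0.25, adjusted p = 0.00102, and adjusted p = 0.461 with an estimated correlation) and the interferon list (-0.21, adjusted p = 0.0176, and adjusted p = 0.551 with an estimated correlation) shifted by less. Of their members 2, 2 and 0 rose and 0, 0 and 1 fell, and adjusted over the list alone 7, 6 and 0 rose and 0, 0 and 1 fell. Pou5f1 rose by 2.21 ± 0.35, and 0 of 35 pluripotency network genes passed, with 0 adjusted over the list alone and Klf2, the largest, at 6.66 ± 1.99 against 9.14 ± 0.13 (SD).

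With the replicate block 2827 genes passed, 1658 higher and 1169 lower, and the Hox list passed (adjusted p = 0.00107, and adjusted p = 0.453 with an estimated correlation). The count was 86 in the 4 compared arrays alone, 97 without replicate 1 of the cohort, 573 without its replicate 2, 358 without control replicate 2 and 506 without control replicate 1. The block called 22 DNA replication, 7 glycolysis and 5 oxidative phosphorylation genes as higher, 16 contractile, 3 interferon and 3 pluripotency genes as lower, and 13 matrix genes as lower and 2 as higher. Of 49 named genes 36 lost their call when some array was left out, Cdh1, Krt14 and Dsp among them.

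**Figure D2:**
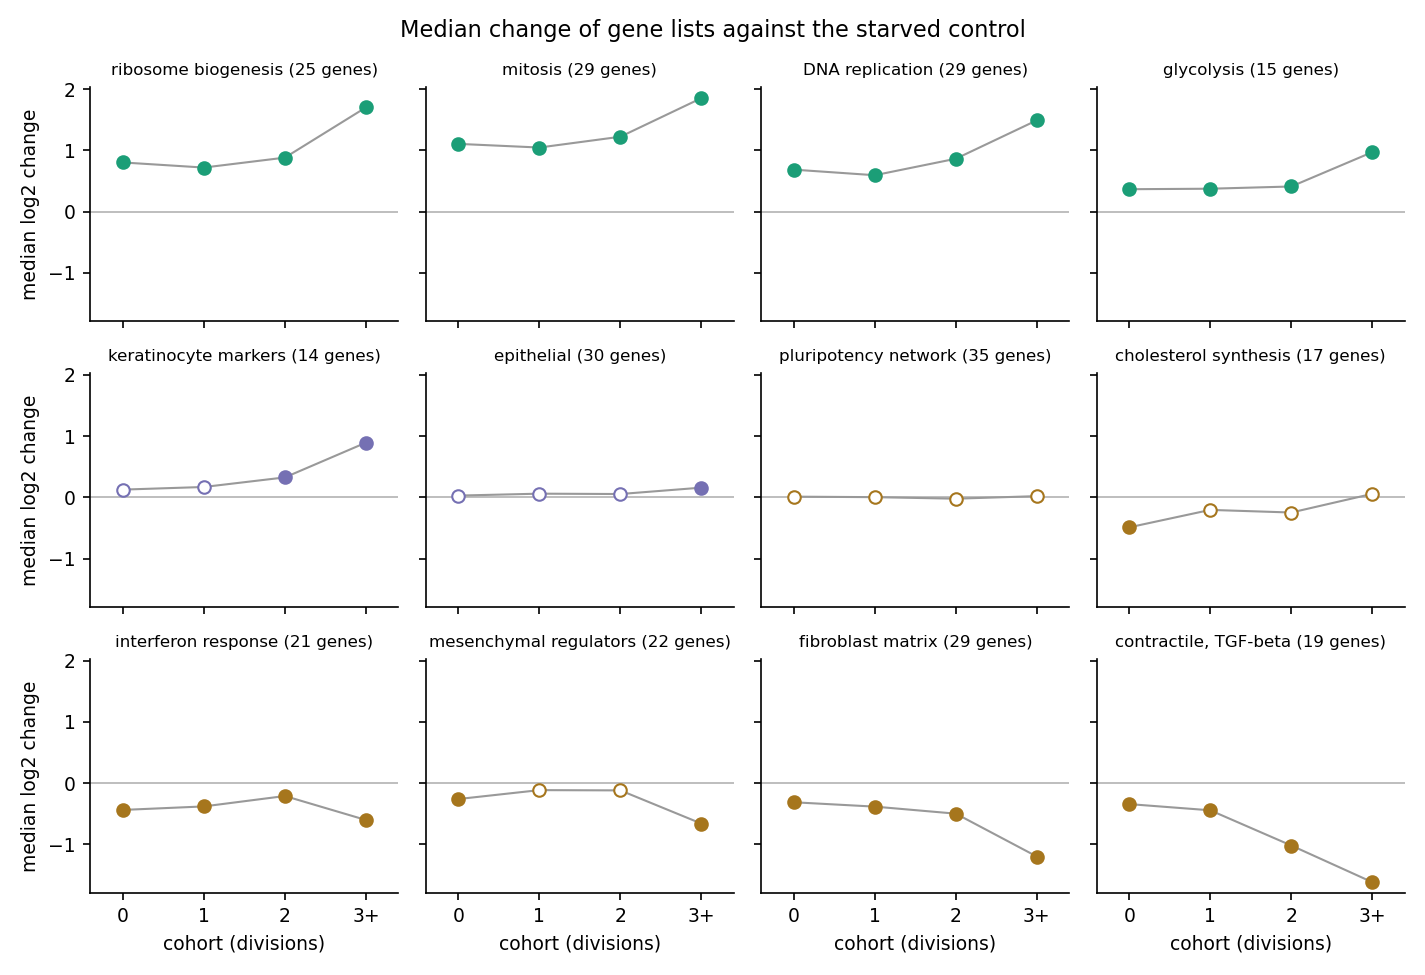
Median log2 change of 12 gene lists against the starved control in the induced cohorts of 0, 1, 2 and 3 or more divisions. Filled points passed limma's camera test with the preset correlation and open points did not, and the median of mitosis genes lay at 1.11 after 0 divisions and at 1.85 after 3 or more, while that of contractile genes fell from -0.34 to -1.62.

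Among induced cells alone, 2 divisions against 0 compared samples registered together and grown in the same serum. Signs of RNA quality differed between them, with an Actb 3-prime minus 5-prime difference of 0.33 and 0.27 after 0 divisions against 0.42 and 0.49 after 2, and 18S readings of 5896 and 5704 against 4218 and 2399. Mal, the apical proteolipid gene, rose from 4.19 ± 0.40 to 9.27 ± 1.02 (SD, n = 2), or 33.8-fold, the collagenase gene Mmp13 rose 10.6-fold, Krt19 8.98-fold, the gluconeogenesis gene Fbp2 7.11-fold, Krt8 5.42-fold and the interferon-inducible gene Ifi202b 4.76-fold. The call of Mmp13 was lost without any 1 of the 4 arrays and those of the other 5 genes without 3 of them. These were the largest of 10 calls, all higher, of which 9 were at least 2-fold. Limma counted 1412 genes at an unadjusted p under 0.05. Contractile and TGF-beta response genes shifted down by a median of -0.67 with 18 of 19 changes below 0 and 0 genes past the test, also adjusted over the list alone (adjusted p = 9.33e-06, and adjusted p = 0.874 with an estimated correlation). Immediate early genes shifted up by 0.36 with 18 of 20 changes above 0, and 3 rose and 1 fell adjusted over the list alone (adjusted p = 0.000184, and adjusted p = 0.126 with an estimated correlation). Keratinocyte markers shifted up by 0.16, with 3 higher adjusted over the list alone (adjusted p = 0.00429, and adjusted p = 0.418 with an estimated correlation). Mitosis genes (median 0.14, adjusted p = 0.0585) and ribosome biogenesis genes (median 0.06, adjusted p = 0.323) did not pass. With the replicate block 205 genes passed, 136 higher and 69 lower, among them 3 immediate early and 1 keratinocyte gene higher and 1 contractile gene lower, and so did the Hox list (adjusted p = 0.0181, and adjusted p = 0.854 with an estimated correlation). The count was 0 with a floor of 16, among the brighter genes, and in the 4 compared arrays alone. It was 0 without replicate 1 of either cohort and 1 without replicate 2 of the 0 division cohort. Without replicate 2 of the 2 division cohort it was 13, 10 higher and 3 lower. The contractile and keratinocyte lists lost their calls without replicate 1 of the 2 division cohort (medians -0.30 and 0.16). Further lists gained a call without replicate 1 of the 0 division cohort, which were DNA replication (median 0.25), Hox (-0.43) and interferon genes (0.25). Mitosis genes (0.17) and cholesterol synthesis (0.37) did without its replicate 2. Without replicate 2 of the 2 division cohort the matrix (-0.17), cholesterol synthesis (0.43) and Hox lists (-0.52) did. These fits without 1 array had no block and left the replicate numbers unbalanced, so their losses and gains may come from the replicate number. In the 4 compared arrays alone mitosis, interferon (both adjusted p = 0.00657) and cholesterol synthesis genes (0.0495) passed. With the block in those arrays mitosis and interferon (both 0.0102), DNA replication and cholesterol synthesis (both 0.0366) and Hox genes (0.00201) passed. Mitosis genes also passed without quantile normalization (0.0311) and with median centring (0.038), cholesterol synthesis without quantile normalization (0.0452) and with the mean of probe sets (0.0416), and epithelial genes among the brighter genes (2.97e-05). Over all arrays, each of the lists gained in these settings had adjusted p = 0.874 with an estimated correlation.

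As a slope over 0, 1 and 2 divisions, 0 of 18193 genes passed limma's test on the 6 arrays, 1561 had an unadjusted p under 0.05, 394 passed with the replicate block, 245 higher and 149 lower, and 1640 passed when the cohort of 3 or more divisions was added with the code 3. Krt19 had a slope of 1.58 ± 0.15 per division (log2, SE, adjusted p = 0.0832, and adjusted p = 0.00658 with the replicate block). The slope of the matrix gene Mfap5 was -0.79 ± 0.20 (adjusted p = 0.334, and adjusted p = 0.00374 with the block). Contractile genes shifted down by a median of -0.34 per division (adjusted p = 2.14e-05), and the immediate early (0.18, adjusted p = 0.000325), keratinocyte (0.08, adjusted p = 0.00306), mitosis (0.07, adjusted p = 0.0113), interferon (0.08, adjusted p = 0.014) and cholesterol synthesis lists (0.11, adjusted p = 0.0449) shifted up. With an estimated correlation the adjusted p of these 6 lists ran from 0.245 to 0.812. Cholesterol synthesis did not pass with the block (adjusted p = 0.0637), while Hox genes did (adjusted p = 0.00327, and adjusted p = 0.456 with an estimated correlation). Without replicate 1 of the 2 division cohort 1 list passed.

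The cohort labelled with 3 or more divisions also differed from that labelled with 0. Mal rose 99.0-fold, Cdh1 43.8-fold, Fetub 40.7-fold, Krt14 30.5-fold, Krt8 28.9-fold and Aldh3a1 25.7-fold. Nrk (-4.05), Plscr2 (-3.98), Agtr2 (-3.78), Egfl6 (-3.75), Npr3 (-3.65) and the glutathione transferase gene Gstt1 (-3.64) fell by the most. This rank holds among called genes whose arrays did not overlap between the cohorts. Pou5f1 rose by 2.17 ± 0.35 (SE). Klf4 fell by 1.34 ± 0.19 on the probe set tested, while its other probe set read 8.99 and 9.01 against 8.88 and 9.05 after 0 divisions. The test called 2529 genes, 1539 higher and 990 lower, and 990 of the calls were at least 2-fold. Signs of RNA quality moved with these cohorts, the Actb 3-prime minus 5-prime difference from 0.33 and 0.27 to 0.45 on both arrays, that of Gapdh from 0.11 and 0.10 to 0.27 and 0.25, and the 18S reading from 5896 and 5704 to 1747 and 1553.

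Ribosome biogenesis genes rose in 20 of 25 cases (25 adjusted over the list alone), with Rrp1b at 1.44 and Dkc1 at 1.35 (adjusted p = 2.51e-13, and adjusted p = 0.271 with an estimated correlation). Mitosis genes rose in 11 of 29 cases (17 adjusted over the list alone), with Aurka at 1.15 (adjusted p = 7.58e-08, and adjusted p = 0.426 with an estimated correlation), and DNA replication genes in 10 of 29 (14 adjusted over the list alone), with Cdt1 at 1.32 (adjusted p = 1.31e-06, and adjusted p = 0.426 with an estimated correlation). Epithelial genes rose in 6 of 30 cases, also adjusted over the list alone, among them Dsp (22.6-fold; adjusted p = 0.00392, and adjusted p = 0.204 with an estimated correlation), and keratinocyte markers in 6 of 14 (9 adjusted over the list alone), with Krt6a at 4.01 (adjusted p = 1.23e-05, and adjusted p = 0.204 with an estimated correlation). Glycolysis (4 of 15 higher, 11 adjusted over the list alone, Pfkp by 1.85; adjusted p = 0.000173, and adjusted p = 0.271 with an estimated correlation), oxidative phosphorylation (6 of 22 higher, 8 adjusted over the list alone; adjusted p = 0.000282, and adjusted p = 0.401 with an estimated correlation) and chromatin regulators (12 higher and 1 lower of 31, 15 and 1 adjusted over the list alone, Hells by 1.17; adjusted p = 0.000208, and adjusted p = 0.401 with an estimated correlation) rose too. Of the cholesterol synthesis genes 3 of 17 rose, Dhcr7 (1.29), Stard4 (1.28) and Lss (0.89), and 5 did adjusted over the list alone (adjusted p = 0.000296, and adjusted p = 0.559 with an estimated correlation).

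Fibroblast matrix genes fell in 12 of 29 cases (19 adjusted over the list alone), with Dpt at -3.22 and Ogn at -2.01 (adjusted p = 8.19e-10, and adjusted p = 0.208 with an estimated correlation). Contractile genes fell in 6 of 19 cases (10 adjusted over the list alone), with Mylk at -2.23 (adjusted p = 9.76e-07, and adjusted p = 0.426 with an estimated correlation), and mesenchymal regulators in 4 of 22 (5 adjusted over the list alone), Osr1 (-1.82), Cdh11 (-1.49) and Twist1 (-1.02) among them (adjusted p = 0.000143, and adjusted p = 0.36 with an estimated correlation). The interferon list shifted by -0.26 with Ifit3 lower (-2.08) and Oas1a higher (0.62), the same counts as adjusted over the list alone (adjusted p = 0.0289, and adjusted p = 0.559 with an estimated correlation). The blocked fit called 4652 genes, 2611 higher and 2041 lower, and the Hox list (adjusted p = 0.00724, and adjusted p = 0.511 with an estimated correlation). The block called 17 mitosis, 17 DNA replication, 11 glycolysis and 5 cholesterol synthesis genes as higher and 20 matrix, 15 contractile, 10 mesenchymal and 4 interferon genes as lower. The count was 391 and 1480 without replicates 2 and 1 of the cohort of 3 or more divisions and 929 and 459 without replicates 2 and 1 of the 0 division cohort. Of 66 named genes 15 stayed past the threshold without any 1 array, Cdh1, Mal, Krt14 and Dpt among them. The 2 cohorts were registered in separate sets, so a batch cannot be told from the group.

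The genes called after 0 divisions and after 3 or more divisions overlapped. Of the 54 genes called after 0 divisions, Dkc1 and Mcm7 among them, 53 were called in the same direction after 3 or more, 40 higher and 13 lower, and 0 in the opposite direction. Independent lists of these sizes would share 6.37 and 1.64 genes, and simulated unchanged groups against the same controls shared a mean of 0 over 100 simulations, a value that says little because groups without effects give almost no calls. Across genes, which are not independent replicates, the log2 changes of the 2 comparisons correlated with r = 0.764 against a simulated 0.499, and their covariance was 0.205 against a simulated 0.0372, which holds the part from the shared controls, a difference of 0.167. Part of the excess of shared calls over independent lists may come from the shared control arrays, which are too few to be split. Of the 1357 genes called at least 2-fold higher after 3 or more divisions, such as Cdh1 and Dkc1, 95.7% lay above the control after 0 divisions, and the median log2 change was 0.52, 0.58, 0.76 and 1.43 after 0, 1, 2 and 3 or more divisions. For the 982 genes called at least 2-fold lower, such as Dpt and Mylk, 95.6% lay below the control after 0 divisions and the medians were -0.46, -0.57, -0.76 and -1.55. These genes were chosen on the cohort of 3 or more divisions and share its control, so their signs are not independent evidence. With the replicate block the overlap was 567 genes, and with only the arrays of each comparison it was 0. It was 4 without replicate 2 of the 0 division cohort, 5 without either replicate of the cohort of 3 or more divisions, 6 without replicate 1 of the 0 division cohort or replicate 2 of the control, and 32 without replicate 1 of the control.

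**Figure D3:**
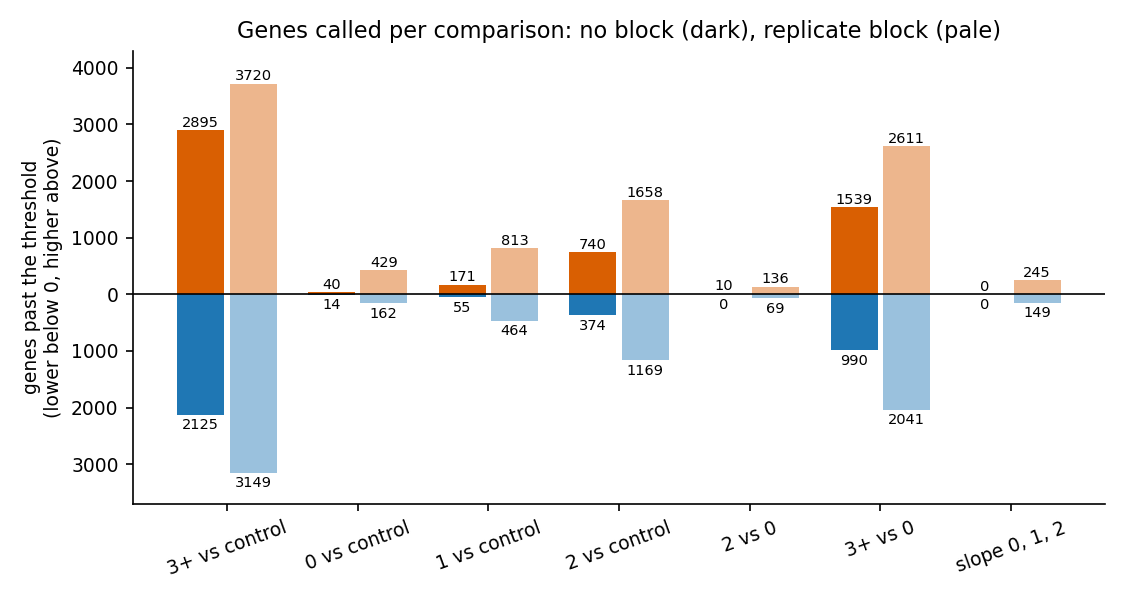
Number of genes past an adjusted p of 0.05 in limma for each comparison, higher above the zero line and lower below it. Dark bars are the fit without a block and pale bars the fit with the replicate number as a block, and the comparison of 0 divisions with the control went from 40 higher and 14 lower to 429 and 162.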

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

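The tests of opposite signs and of unnamed probe sets were chosen after the data were seen. Cholesterol synthesis genes differed between cohorts in their effect against the control. Their median log2 change was -0.49 after 0 divisions and 0.06 after 3 or more, and the test between the cohorts gave a median difference of 0.63 (camera adjusted p = 0.000296, and adjusted p = 0.559 with an estimated correlation), with all 17 genes higher in the cohort of 3 or more divisions, Dhcr7, Stard4 and Lss past the single-gene test. The 2 cohorts were registered in separate sets.

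For 397 genes the effects against the control had opposite signs after 0 and after 3 or more divisions and the difference between the cohorts passed limma's test, 253 lower and then higher, 144 higher and then lower. Only 1 of the 397 passed by itself after 0 divisions, and 290 did after 3 or more, so the count rests mostly on signs of changes after 0 divisions that did not pass. Ranked by the smaller of both effects, a rank chosen after the values were seen, the first was Lama3, a laminin gene of epithelial basement membranes, at -0.97 after 0 divisions and 1.21 after 3 or more (difference 2.17 ± 0.21, SE, adjusted p = 0.00212). Gm15866 came next at 0.73 and -2.88 (difference -3.62 ± 0.25, adjusted p = 0.00104). For both genes the change after 0 divisions did not pass by itself (adjusted p = 0.114 and 0.289).

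Probe sets that name no single gene were left out of the comparisons and also carried signal. After 3 or more divisions 450 of 10092 such probe sets were higher than the control and 531 lower in limma's test over all probe sets. These 981 calls were a smaller share than that of the whole test. It called 9304 of the 45101 probe sets in the table, with 64 control ones left out.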

How the results depend on the processing

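No named gene changed direction past its threshold under any setting in which it was followed. The same held for lists past the threshold in 3 contrasts, 3 or more and 0 against the control and 2 against 0. Reversals were not tracked for other lists. The settings without quantile normalization, with the block in the compared groups only, and with the block and estimated correlation were chosen after seeing the data, and where no cause is named below the cause was not tested. For the 6 contrasts in the order 3 or more, 0, 1 and 2 divisions against the control, then 2 and 3 or more against 0, the main counts were 5020, 54, 226, 1114, 10 and 2529, with 0 for the slope and 53 for the overlap. With the replicate block the pairing raised them from 54 to 591, 226 to 1277, 1114 to 2827, 10 to 205, 2529 to 4652, the slope to 394 and the overlap to 567, and 5020 to 6869. Besides the Hox list in each contrast and slope, and cholesterol synthesis in the slope, the block changed the call of no other list. With the block in the compared groups only the counts were 451, 1264, 1929, 184 and 4436, the overlap 422, and 8 lists for 2 against 0. Without the block in the compared groups only, where fewer arrays leave fewer degrees of freedom, 0, 0, 86 and 0 genes passed for 0, 1 and 2 against the control and 2 against 0, the overlap was 0, and 6 lists passed for 2 against 0. The slope with 8 arrays called 1640 genes and 13 lists.

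Median centring gave 25 genes for 0 against the control, 16 higher and 9 lower, and an overlap of 24. A floor of 16 gave 21, 0 for 2 against 0, and an overlap of 21. Testing each probe set, over more features, gave 9304, 1871, 22 and 4184 for 3 or more and 2 against the control and 2 and 3 or more against 0. Leaving out probe sets ending in _x_at or _s_at gave 5 for 2 against 0. Genes above the median of all genes by mean, with fewer genes tested, gave 88 for 0 against the control, 75 higher and 13 lower, 0 for 2 against 0, and an overlap of 86. Trend and robust eBayes gave 82 and an overlap of 80. No quantile normalization gave 5 lists for 2 against 0 and moved no count of genes by over 1.5 times. Of single lists, followed for 3 or more and 0 against the control and for 2 against 0, chromatin regulators for 0 lost the call without probe sets ending in _x_at or _s_at (adjusted p = 0.0699).

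An adjusted p under 0.01 gave 2890, 4, 8, 188, 0 and 663 in the order above, and requiring 2-fold gave 2339, 150, 543 and 990 for 3 or more, 1 and 2 against the control and 3 or more against 0. With an estimated correlation 0 lists passed in each contrast and in the slope, with and without the block. Fry, which tests the list alone, passed 4 lists for 0 against the control and 0 for 2 against 0 and for the slope. The 4 were the ribosome biogenesis, mitosis, DNA replication and oxidative phosphorylation lists, all shifted up.

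Leaving out 1 array, with the lone sample assumed to vary like the other groups, gave 2701 to 4025 genes for 3 or more against the control, 4 to 32 for 0, 4 to 77 for 1, 97 to 573 for 2, 0 to 13 for 2 against 0, 391 to 1480 for 3 or more against 0, 0 to 0 for the slope and 4 to 32 for the overlap. The count of lists ran from 1 to 6 for 2 against 0 and from 1 to 7 for the slope. The fits without 1 array had no block, so the replicate number may account for part of these changes. Single named genes were counted over the settings in which they were followed, which leave out the stricter thresholds for genes. They kept their side of the threshold in 4229 cases, lost the call in 654 and gained it in 95. For the single lists of these 3 contrasts the counts were 957, 14 and 34. The list counts leave out fry and the estimated correlation, with which 0 lists passed. With 2 arrays per group and no detection calls, changes of genes near background could not be measured on both sides.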

Other observations

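All tests in this part were chosen after the data were seen, except the list of imprinted genes, which was written down before its values were read. The largest structure beside the cohorts was the replicate number. With the groups as covariates 2173 genes differed between replicate 2 and replicate 1, 1140 higher and 1033 lower, and 293 of them at least 2-fold. The imprinted growth regulator gene Grb10 was higher in replicate 2 by 4.55 ± 0.20 (log2, SE) and in 5 of 5 groups, with a range of 4.14 to 5.63. The noncoding RNAs Meg3 (3.41 ± 0.25), Xist (3.38 ± 0.33) and Rian (2.26 ± 0.21) and the secreted protein gene Cthrc1 (3.52 ± 0.38) were higher in 5 of 5 groups too. Sned1 (-3.94 ± 0.30), Cyp2f2 (-3.45 ± 0.26) and the growth factor gene Igf2 (-1.90 ± 0.26) were lower in each group. Of the Hox genes, which mark position along the body axis, 6 of 6 Hoxc, 5 of 6 Hoxb and 2 of 4 Hoxd genes were higher in replicate 2, Hoxc8 by 2.29 and Hoxc10 by 2.07. Of 7 Hoxa genes 1 was higher and 2 lower, Hoxa10 by -0.58, and a difference between clusters was not tested.

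For this split by replicate number 3 explanations were set against the tables. RNA quality that follows the replicate number stays open, since only 1 of 3 signs, the 18S reading, differed the same way in all 5 groups, while the Actb and Gapdh 3-prime minus 5-prime differences were higher in replicate 1 in 3 and 4 of 5. Cells of the other sex mixed into the replicate 2 cultures may contribute, as the Y-linked genes Eif2s3y and Uty were lower in replicate 2 in 5 of 5 groups, with a median of -0.37, beside the higher Xist. A different state of the imprinted Dlk1-Meg3 cluster may also contribute, as its further RNA Mirg was higher in replicate 2 by 0.70 ± 0.14 (SE) in 5 of 5 groups. Dlk1 of the same cluster did not pass limma's test (-0.37 ± 0.28, adjusted p = 0.453). It was higher in replicate 2 in 2 of 5 groups. All 3 explanations stay open and were not tested on the Hox genes. The labels, which call the numbers biological replicates in 2 groups, do not say how they differ.

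Growth genes stood higher in the 0 division cohort than in the control, although its cells were labelled with an average of 0 divisions. A share of cells like the cohort of 3 or more divisions was argued against. The 16 called epithelial and keratinocyte genes had reached a median of 1.36% and 2.44% of their later linear rise in replicates 1 and 2. The 75 called growth genes had reached 40.9% and 34.7%. Cells like the cohort of 1 division were not covered by this test. In that cohort growth genes had reached 41.6% and 32.3%, and epithelial and keratinocyte genes 4.19% and 12.4%. Cells that had divided within a cohort with an average of 0 divisions therefore stay open as a source. The serum difference between the cohorts and the control may be a source and cannot be told apart from the group, since 0 uninduced arrays were in the serum of the cohorts. Nor can a difference between the 2 sets of registered samples, as 0 groups had arrays in both sets. The induced factors, Myc among them, remain a biological explanation that was not tested apart from serum.

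Epidermal keratin genes were higher after 3 or more divisions, Krt14 by 6.04. Keratinocytes mixed into that cohort stay open, since 9 of 14 markers rose, with a median change of 0.89, Krt17 (2.75) and Lgals7 (3.15) among them. Others did not pass, as Krt5, an abundant partner of Krt14 in basal keratinocytes, read 5.18 against 5.20 in the control, and Krt10, Trp63, Dsc3 and Lor did not pass either. Induction itself may be the source too and was not tested apart from serum and division.

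Imprinted genes were tested as a list against the control after 3 or more divisions, because imprinted genes such as Cdkn1c had been seen among the falls, and genes seen already were left out. Of 27 measured genes 7 fell, Sgce by -2.72 ± 0.35 (SE), Ndn by -1.82 ± 0.15, Mest by -1.43 ± 0.32 and Plagl1 by -1.30 ± 0.17 among them, and 3 rose, led by Slc38a4 (1.84 ± 0.21). The median was -0.06 and limma's camera gave an adjusted p of 0.0779, with 1 list to adjust over, so the list as a whole did not pass, and 14 of its genes lay below the median intensity of all genes.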
